A study of Homo sapiens with 18 samples.

How the data were processed

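RNA of MOLM-13 cells was sequenced in 18 samples, 3 in each of 6 groups, given DMSO, IACS-9571 or dTRIM24 for 4 h or 24 h. Groups were taken from the sample titles and time points. The labels' treatment protocol gives 24 h for each sample, while titles, time points and the series design give 4 h or 24 h, and the latter were followed. Doses are not given in the sources used here. Per the labels' protocols, samples were normalized by cell count and mixed with ERCC spike-ins, and an Illumina NextSeq instrument was used. Nothing in the labels says whether the samples of a group came from separate cultures.

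The deposited table holds FPKM values that the authors made with TopHat2 and Cuffnorm on hg19, per the submitters' processing notes; versions, annotation and strand handling are not given in the sources used here. It has 1 column per group, named as a mean, and 23713 rows. No value is 0 and 6066 rows share 1 value per column, between 0.0914 and 0.105 FPKM, near the lowest value of the table (0.0878 FPKM), as if a constant had been added. Of the 92 spike-in rows, 25 have at least 5 FPKM in each group. Their median lies at nearly the same level in all columns (deviation 1.92% or less) while column totals differ, as if values had been scaled to the spike-ins; single spike-ins differ by up to 0.88 on the log2 scale. Both points come from the values alone. The table gives no counts, so depth is unknown and no counting interval can be given.

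Spike-ins and 1721 rows of small RNAs, chosen by name, were left out of the comparisons. Genes with a highest group value of at least 1 FPKM were kept, 11051 in all. Differences were of log2(FPKM + 1) between group means, with a threshold of 1 (2-fold). The planned limma and gene set tests need values per library, so the rule fixed for means was used: no test, no p-value across genes, and for a gene list of at least 5 kept members its median with the percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these means. The lists, the threshold, the comparisons and the rule for named genes were fixed before the data were examined.

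Named genes were TRIM24 and its list; up to 10 genes each way past 2-fold with at least 5 FPKM in the higher group in each of the 6 comparisons of compounds; up to 4 members with the largest differences of each list described; and up to 10 genes each way past 2-fold with dTRIM24 against both references. Genes named outside this rule were chosen after their values were seen: CA2 and CD38 beside other groups, HMOX1 and H2AFZ, H2AFX and H3F3B with dTRIM24 at 4 h, EIF3C beside a copy, MALAT1 among the genes past 2-fold with dTRIM24 against both references, H3F3A, H3F3B and HYPK in DMSO, STARD4 as an exception in its list, and members of a list shown for a second comparison.

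The box reference, GENCODE transcripts of another build than the authors', gave only GC content and length of the transcripts, by gene symbol, for 10245 genes (92.7% of those kept), and no coordinates are printed. A cubic trend of the log2 difference on GC content was taken out as an alternative chosen after the data were seen. RNAs lacking a poly(A) tail were named as HIST genes, RMRP, RPPH1, SNAR genes, TERC and BCYRN1; MALAT1, which also lacks one, was not among them.

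The lists covered the TRIM24 and BRPF1 targets, the VHL complex, HIF targets, interferon, retinoic acid, p53, cell cycle, MYC and ribosome biogenesis, HOXA and MEIS1, myeloid differentiation, NF-kB, immediate early, ATF4, unfolded protein response, cholesterol and SREBP, LXR, NRF2, metallothionein, heat shock, proteasome, BCL2 family, BET bromodomain markers, histones, oxidative phosphorylation, ribosomal proteins, MHC class II, housekeeping and mitochondrial genes, and markers of 4 other cell sources. The alternatives tried were pseudocounts of 0.1 and 0.5, no filter on low values, a floor of 5 FPKM, median centring, quantile normalization, rescaling to the spike-ins and a 1.5-fold threshold.

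The steps were tested on simulated data for dTRIM24 against DMSO at 4 h with 11051 genes. Of 100 genes changed 2.5-fold 83% were called, and of 100 changed 4-fold 100%, with 0 calls among 10851 unchanged genes. The noise was that of the spike-ins with at least 5 FPKM (SD of differences 0.21), so 0 false calls was nearly fixed in advance. Changed genes were drawn from those with at least 5 FPKM in DMSO. Changes of lower genes, and errors from copies or overlapping genes, were not simulated. Of 100 random lists 7 fell outside the 2.5 to 97.5 percentiles. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.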

Results

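RNA was sequenced from MOLM-13, a human acute monocytic leukaemia line, after 4 h or 24 h with DMSO (the solvent control), IACS-9571 or dTRIM24. IACS-9571 binds the bromodomains of TRIM24 and BRPF1, readers of acetylated histones. dTRIM24 joins a bromodomain ligand to a ligand of VHL, the substrate receptor of a ubiquitin ligase, so that TRIM24 protein can be degraded. The labels name 18 samples in 6 groups of 3, and the deposited table holds 1 mean FPKM per gene and group. FPKM are by definition read fragments scaled by transcript length and library size. Values per library were not analysed here, so no value below has a replicate error, no difference was tested, and the read depth is unknown. For scale, 25 ERCC spike-ins, RNAs of known sequence added to each sample, were compared too. Their log2 differences had an SD between 0.11 and 0.22 in the 9 comparisons. This is the spread of single RNAs between group means and cannot stand in for a replicate error. Several list medians below are smaller than this SD, even where their percentile is high. Examples at 4 h are 0.05 for HOXA and MEIS1 genes (IACS-9571 against DMSO) and 0.06 for unfolded protein response genes (dTRIM24 against IACS-9571). A percentile describes these means and gives no replicate error either. Differences are of log2(FPKM + 1), which understates the change of low genes, and "past 2-fold" means a difference of at least 1 on that scale among 11051 kept genes. Column totals lay between 771830 FPKM (IACS-9571, 24 h) and 1058351 FPKM (DMSO, 4 h), while the spike-in medians nearly matched. The values thus look scaled to the spike-ins and not to library size alone.

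TRIM24 mRNA, whose protein is the target of both compounds, was present at 14.6 FPKM in DMSO, 17.6 FPKM in IACS-9571 and 17.3 FPKM in dTRIM24 at 4 h. At 24 h it stood at 13.97 FPKM in DMSO, 14.03 FPKM in IACS-9571 and 17.2 FPKM in dTRIM24. A degrader acts on protein, so these mRNA levels do not check the labels. Of the 11 kept genes of the TRIM24 family and of the BRPF1 acetyltransferase complexes, none passed 2-fold in the 6 comparisons of compounds. TRIM28, a TRIM24 relative, had 170 FPKM in DMSO, 152 FPKM in IACS-9571 and 138 FPKM in dTRIM24 at 4 h. With dTRIM24 at 4 h the log2 differences from DMSO were 0.23 for TRIM24, -0.30 for TRIM28, 0.11 for TRIM33, -0.15 for BRPF1, 0.02 for BRPF3, -0.07 for BRD1, 0.09 for KAT6A, 0.08 for KAT6B, -0.04 for KAT7, -0.15 for ING5 and 0.00 for MEAF6. The median of the list at 4 h was 0.02 with IACS-9571 (percentile 70.2). At 24 h it was 0.03 with IACS-9571 and 0.38 with dTRIM24 (percentile 93.6; 0.10 with the trend on transcript GC content taken out).

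The 4 h comparison of IACS-9571 with DMSO asks what the bromodomain ligand does early. Sterol synthesis genes were higher together: all 23 kept genes of the cholesterol synthesis and SREBP list lay above DMSO, and 16 of them passed 2-fold. HMGCS1, the synthase at the head of the mevalonate pathway, went from 20.7 FPKM to 108 FPKM. SQLE, the squalene epoxidase, went from 25.2 FPKM to 97.0 FPKM, and INSIG1, a sterol-regulated retention protein of the endoplasmic reticulum, from 60.9 FPKM to 226 FPKM. MSMO1, a sterol demethylating enzyme, went from 16.7 FPKM to 56.7 FPKM. The median of the list was 1.32, at percentile 100 among 10000 random lists matched on expression, and 1.28 with the trend on transcript GC content taken out.

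HMOX1, the haem oxygenase, was also higher with IACS-9571 at 4 h, at 15.2 FPKM against 2.27 FPKM in DMSO. It belongs to the NRF2 and oxidative stress list, of which 13 of 14 kept members lay above DMSO and 1 passed 2-fold. ME1, a cytosolic malic enzyme, had 17.9 FPKM against 11.5 FPKM, FTH1, the ferritin heavy chain, 492 FPKM against 371 FPKM, and GCLM, of glutathione synthesis, 21.3 FPKM against 16.4 FPKM. The median of this list was 0.23 (percentile 100), and 0.21 with the GC trend taken out. Monocyte and granulocyte differentiation genes had a median of -0.17 (percentile 0; -0.12 with the GC trend taken out) and none of the 19 passed 2-fold. Among them PRTN3, a granule protease, had 314 FPKM against 430 FPKM, and SPI1, a myeloid transcription factor, 65.4 FPKM against 80.1 FPKM. In this list 16 members lay below DMSO and 3 above, the highest by 0.36. The HOXA and MEIS1 program of MLL-fusion leukaemia had a median of 0.05 (percentile 99.4), with HOXA7 at 7.13 FPKM against 5.79 FPKM.

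In all, 28 genes were higher and 4 lower past 2-fold with IACS-9571 at 4 h. Besides the 16 genes of the sterol list, the higher ones included 6 RNAs that lack a poly(A) tail, among them RPPH1, the RNA of RNase P, at 10.7 FPKM against 2.01 FPKM. SNAR-A6 had 5.51 FPKM against 0.0945 FPKM, and SNAR-A1, SNAR-A2, SNAR-A12 and SNAR-A13 shared 1 value, 5.27 FPKM against 0.0945 FPKM. SNAR-B1 was lower, at 6.98 FPKM against 18.4 FPKM. The SNAR genes are near-identical copies, so their separate values are uncertain. The differences ran with transcript GC content (Spearman rho across genes -0.39). With the GC trend taken out, over 10245 genes with a GC value, 24 were higher and 0 lower.

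**Figure D1:**
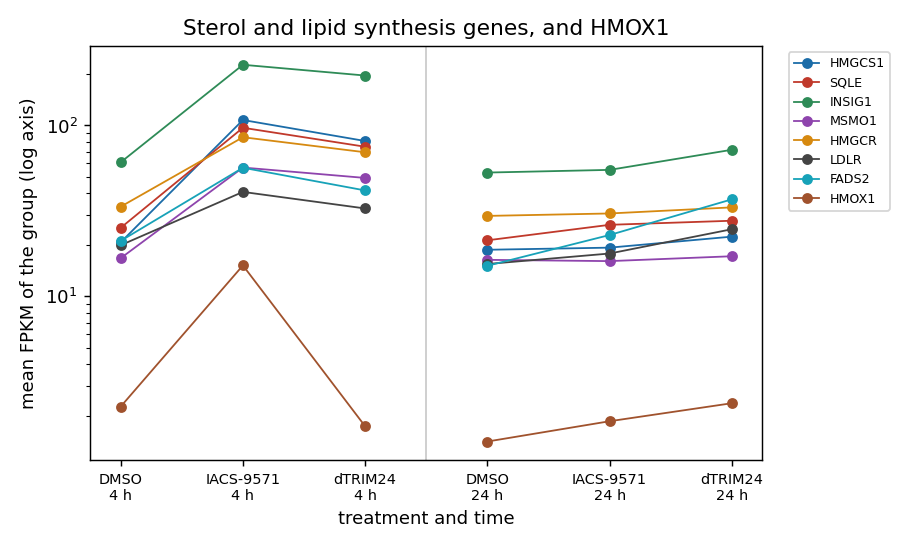
Mean FPKM (log axis) of 7 sterol and lipid synthesis genes and of HMOX1 in the 6 groups, 4 h on the left and 24 h on the right; each point is the authors' mean and no error is known. HMGCS1 stands at 20.7 FPKM in DMSO, 108 FPKM in IACS-9571 and 81.1 FPKM in dTRIM24 at 4 h, while HMOX1 is higher in IACS-9571 alone among the 4 h groups.

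With dTRIM24 at 4 h the same list of sterol genes stood above DMSO, with all 23 kept members higher and 12 past 2-fold. HMGCS1 had 81.1 FPKM against 20.7 FPKM, INSIG1 196 FPKM against 60.9 FPKM, SQLE 75.1 FPKM against 25.2 FPKM and MSMO1 49.3 FPKM against 16.7 FPKM. The median of the list was 1.01 (percentile 100; 1.02 with the GC trend taken out). HMOX1 was at 1.74 FPKM against 2.27 FPKM, and the NRF2 list had a median of -0.03 (percentile 45.8) with none of its members past 2-fold. Differentiation genes had a median of -0.15 (percentile 0.60, and -0.10 with the GC trend taken out). AZU1, a granule protein, had 737 FPKM against 1029 FPKM and ELANE, the neutrophil elastase, 821 FPKM against 1057 FPKM. Against DMSO at 24 h this list had a median of -0.10 with IACS-9571 (percentile 3.20, and -0.11 with the GC trend taken out). With dTRIM24 at 24 h it was 0.23 (percentile 52.1), and -0.12 with the GC trend taken out. The low value with dTRIM24 at 24 h thus appears only with the trend taken out.

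Most of the RNAs past 2-fold with dTRIM24 at 4 h were of another kind. Of the 74 higher ones, 58 lack a poly(A) tail, and 50 of these are replication-dependent histone genes, whose mRNAs end in a stem-loop. RMRP, the RNA of RNase MRP, had 1196 FPKM against 12.7 FPKM in DMSO, and RPPH1 had 493 FPKM against 2.01 FPKM. Among the histone genes, HIST2H3A had 36.8 FPKM against 0.521 FPKM, HIST2H4A 54.6 FPKM against 1.59 FPKM and HIST2H4B 55.1 FPKM against 1.59 FPKM. In the histone list 13 of 18 kept members passed 2-fold, with a median of 2.59, and 2.69 with the GC trend taken out. The polyadenylated H2AFZ and H3F3B differed by -0.06 and -0.02, and H2AFX, another histone gene, by -0.16. SNAR-A6 had 28.0 FPKM against 0.0945 FPKM, and SNAR-A1, SNAR-A2, SNAR-A12 and SNAR-A13 had 35.8 FPKM against 0.0945 FPKM each. Of the 232 small RNAs kept out of the comparisons that reached 1 FPKM in a group, 109 were past 2-fold higher and 34 lower. Against DMSO the same RNAs had 52 higher and 40 lower with IACS-9571 at 4 h, 43 and 66 with IACS-9571 at 24 h, and 70 and 47 with dTRIM24 at 24 h.

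Without the RNAs lacking a tail, an alternative chosen after the data were seen, 16 genes were higher and 2 lower with dTRIM24 at 4 h. These 16 include MALAT1, a nuclear long noncoding RNA that was not in the classes left out though its end is cut by RNase P and carries no poly(A) tail. The lower genes, SRGAP2B and RNF5, have near-identical copies elsewhere in the genome and are uncertain: SRGAP2B had 0.535 FPKM against 3.11 FPKM and RNF5 had 1.31 FPKM against 3.89 FPKM. The differences ran with transcript GC content (Spearman rho across genes -0.73; genes are not independent replicates), from a median of 0.12 in the lowest to -0.22 in the highest of 10 GC bins.

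**Figure D2:**
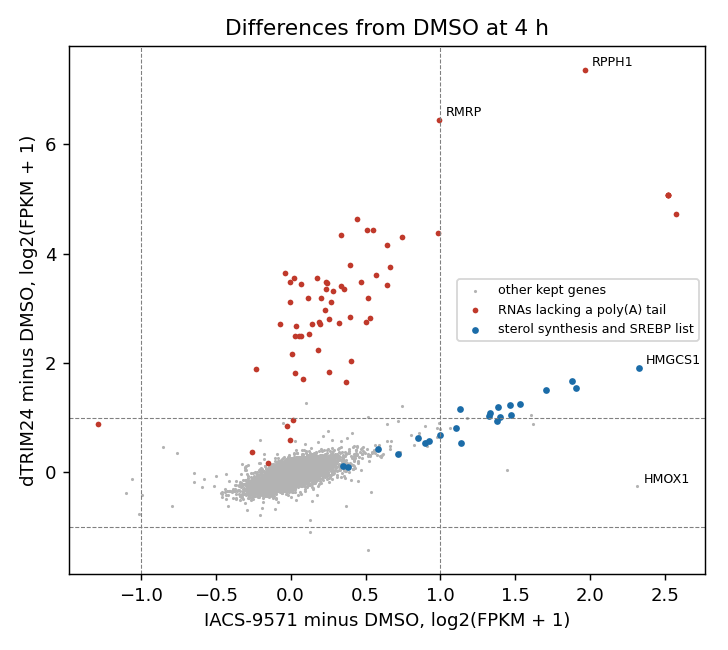
Log2 differences from DMSO at 4 h for each kept gene, IACS-9571 on the x axis and dTRIM24 on the y axis, with the 2-fold bounds as dashed lines. Sterol genes lie high on both axes, HMGCS1 at 2.32 and 1.92, while RMRP and RPPH1 reach 6.45 and 7.36 on the dTRIM24 axis; both axes share the DMSO group.

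The compounds share a bromodomain ligand type and differ by the VHL part of dTRIM24. Their direct comparison at 4 h is at matched time, but the labels give no doses. HMOX1 was lower with dTRIM24 than with IACS-9571, by -2.56, and it was the 1 gene past 2-fold lower with at least 5 FPKM. The NRF2 list had a median of -0.26 (percentile 0; -0.19 with the GC trend taken out), with FTH1 at 339 FPKM against 492 FPKM. Sterol genes were lower in 22 of 23 cases, by a median of -0.29 (percentile 0; -0.24 with the GC trend taken out), and none passed 2-fold. MVD, a mevalonate pathway decarboxylase, had 18.9 FPKM against 29.03 FPKM and MVK, the mevalonate kinase, 23.2 FPKM against 31.4 FPKM. STARD4, a sterol carrier, was the member not lower, at 10.7 FPKM against 10.5 FPKM. Differences in this contrast ran with GC content too (Spearman rho across genes -0.62).

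Of 62 genes higher with dTRIM24 than with IACS-9571 at 4 h, 59 are histone, RMRP, RPPH1 or SNAR genes, and 4 genes were lower. RMRP stood 5.46 and RPPH1 5.40 above IACS-9571. HIST2H3A stood 4.19, HIST2H4A 3.91 and HIST2H4B 3.89 above IACS-9571. HIST1H3B had 26.2 FPKM against 0.701 FPKM, HIST1H2AJ 18.6 FPKM against 0.520 FPKM, HIST2H2BF 23.2 FPKM against 1.05 FPKM, HIST1H2AH 13.6 FPKM against 0.268 FPKM and HIST1H1B 21.4 FPKM against 0.960 FPKM. Without the RNAs lacking a tail, 3 genes were higher and 4 lower. NF-kB and inflammatory genes had a median of -0.14 (percentile 0.30; -0.09 with the GC trend taken out), with NFKB2 at 2.47 FPKM against 4.24 FPKM. Unfolded protein response genes had a median of 0.06 (percentile 99.9; 0.10 with the GC trend taken out), with DNAJB9, a chaperone of the endoplasmic reticulum, at 12.1 FPKM against 8.74 FPKM.

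**Figure D3:**
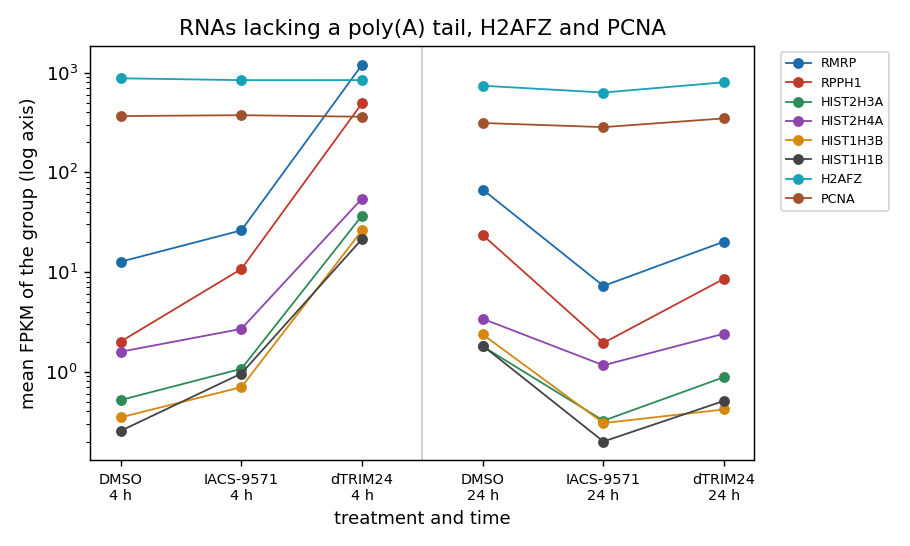
Mean FPKM (log axis) of 6 RNAs lacking a poly(A) tail, and of polyadenylated H2AFZ and PCNA, in the 6 groups; each point is the authors' mean and no error is known. RMRP is at 12.7 FPKM in DMSO, 26.2 FPKM in IACS-9571 and 1196 FPKM in dTRIM24 at 4 h, and at 67.1, 7.25 and 20.2 FPKM at 24 h.

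The calls of both compounds against DMSO at 4 h overlapped in 19 higher genes, out of 28 and 74. Of these 19, 12 are sterol genes and 6 lack a tail. Independent lists of these sizes would share 0.187 genes. Simulated unchanged groups against a common control shared 0, but unchanged genes gave 0 calls in the simulated data, so this value says nothing about the shared control. Both compounds were compared with the same DMSO mean, which cannot be split here, so part of the excess may come from it.

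After 24 h with IACS-9571 few genes stood apart from DMSO: 2 were higher and 17 lower. CA2, a carbonic anhydrase, had 26.2 FPKM against 8.83 FPKM, and in dTRIM24 it stood at 18.02 FPKM. Of the 17 lower genes 15 lack a poly(A) tail. RMRP had 7.25 FPKM against 67.1 FPKM and RPPH1 had 1.95 FPKM against 23.5 FPKM. SNAR-A6 (0.0976 FPKM against 14.1 FPKM), SNAR-B1 (0.0950 FPKM against 12.6 FPKM) and the copies SNAR-A1, SNAR-A2, SNAR-A12 and SNAR-A13 (0.0975 FPKM against 13.5 FPKM each) were near 0.1 FPKM with IACS-9571, close to the value that 6066 rows share in each column. SLX1A, a nuclease subunit with a near-identical copy, had 5.68 FPKM against 13.2 FPKM. Without the RNAs lacking a tail, 2 genes were higher and 2 lower.

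Sterol genes were close to DMSO again at 24 h with IACS-9571, with a median of 0.05 (percentile 100) and none past 2-fold. FADS2, a fatty acid desaturase, had 22.9 FPKM against 15.1 FPKM and FADS1 had 12.1 FPKM against 8.84 FPKM. MYC and ribosome biogenesis genes had a median of 0.07 (percentile 100; 0.09 with the GC trend taken out), with MYC at 207 FPKM against 168 FPKM. ATF4 and integrated stress response genes had a median of -0.13 (percentile 0.01, and -0.11 with the GC trend taken out). PSAT1 had 161 FPKM against 194 FPKM and ASNS 61.9 FPKM against 73.5 FPKM. In this list 20 members lay below DMSO and 4 above, the highest by 0.27. Cell cycle genes had a median of -0.11 (percentile 0.26; -0.08 with the GC trend taken out).

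After 24 h with dTRIM24 the values of most genes were above DMSO, by a median of 0.26, while the spike-ins had a median of -0.06. The median of kept genes at 24 h was 9.97 FPKM in DMSO, 9.88 FPKM in IACS-9571 and 12.4 FPKM in dTRIM24. At 4 h it was 12.2, 12.2 and 12.1 FPKM in the same order. The 24 h groups that stood apart from the 4 h level were thus DMSO and IACS-9571. As deposited, 15 genes were higher and 7 lower. With each group centred on its median, 5 were higher and 19 lower, with quantile normalization 5 and 17, and with the GC trend taken out 2 and 16. FADS2 had 37.0 FPKM against 15.1 FPKM (1.24, or 0.98 relative to the median of all genes). SNHG12, a small nucleolar RNA host gene, had 12.5 FPKM against 4.79 FPKM and MED18, a Mediator subunit, 12.3 FPKM against 5.35 FPKM. P2RY11, a purine receptor, had 8.45 FPKM against 3.62 FPKM, and is uncertain because it overlaps the read-through gene PPAN-P2RY11. GIGYF1 had 6.27 FPKM against 2.61 FPKM and the duplicated PKD1P1, which is uncertain, 6.31 FPKM against 2.41 FPKM. NPIP, duplicated too, differed by 1.05. Relative to the median of all genes SNHG12 stood at 0.97, MED18 at 0.81, P2RY11 at 0.78 and GIGYF1 at 0.75. On that scale PKD1P1 stood at 0.84 and NPIP at 0.80, so all of these lay below the 2-fold bound. HYPK, which shares its locus with a read-through gene, had 27.7 FPKM against 4.49 FPKM.

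Lower with dTRIM24 at 24 h were RMRP, at 20.2 FPKM against 67.1 FPKM, RPPH1, at 8.57 FPKM against 23.5 FPKM, SNAR-B1, at 0.102 FPKM against 12.6 FPKM, SLX1A, at 3.31 FPKM against 13.2 FPKM, and EEF1E1-MUTED, a read-through gene, at 1.55 FPKM against 6.74 FPKM. Histone genes had a median of -0.13 (percentile 0; -0.37 with the GC trend taken out), and 2 of 18 kept members were past 2-fold lower. HIST1H3B had 0.419 FPKM against 2.37 FPKM.

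Relative to the all-gene median of 0.26, MYC and ribosome biogenesis genes stood higher with dTRIM24 at 24 h, with a median of 0.43 (percentile 100). PPAN, a nucleolar protein whose gene also overlaps PPAN-P2RY11, had 42.8 FPKM against 24.97 FPKM and MYC 259 FPKM against 168 FPKM. ATF4 genes had a median of 0.39 (percentile 99.96), with DDIT4 at 229 FPKM against 150 FPKM. The sterol list had a median of 0.37 (percentile 99.7) and NRF2 genes 0.39 (percentile 99.2). FASN, the fatty acid synthase, had 56.1 FPKM against 31.8 FPKM. The differences ran with GC content (Spearman rho across genes 0.61), from a median of 0.13 to 0.48 across the 10 GC bins. With the trend taken out the medians of these lists were 0.08, 0.05, 0.14 and 0.10.

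**Figure D4:**
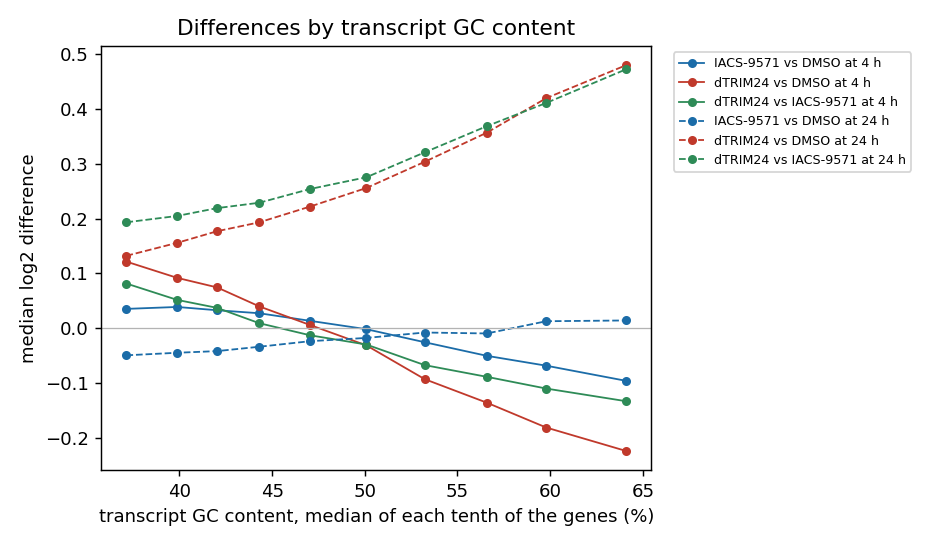
Median log2 difference (y axis) against transcript GC content in % (x axis) for 10 bins of the 10245 genes with a GC value, in the 6 comparisons of compounds; solid lines are 4 h and dashed lines 24 h. For dTRIM24 against DMSO the medians run from 0.12 down to -0.22 at 4 h and from 0.13 up to 0.48 at 24 h.

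Set against IACS-9571 at 24 h, dTRIM24 had a median difference of 0.28 over all genes, with 22 genes higher and 2 lower. The counts were 12 and 2 with median centring, 12 and 3 with quantile normalization and 5 and 2 with the GC trend taken out. Named by size, SNAR-A6 had 6.82 FPKM against 0.0976 FPKM, SNAR-A1, SNAR-A2, SNAR-A12 and SNAR-A13 had 6.52 FPKM against 0.0975 FPKM each, RPPH1 8.57 FPKM against 1.95 FPKM and RMRP 20.2 FPKM against 7.25 FPKM. HYPK had 27.7 FPKM against 6.29 FPKM, and BLOC1S5, which overlaps the read-through gene EEF1E1-MUTED, 15.3 FPKM against 3.71 FPKM. H3F3A, a histone gene with processed copies, had 163 FPKM against 78.7 FPKM. Relative to the median of all genes H3F3A stood at 0.76, below the 2-fold bound. EEF1E1-MUTED was lower, at 1.55 FPKM against 10.1 FPKM.

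Cell cycle genes lay above the all-gene shift in this contrast, with a median of 0.36 (percentile 98.98, and 0.10 and percentile 100 with the GC trend taken out). Against DMSO the list had a median of -0.11 with IACS-9571. With dTRIM24 it was 0.25 (percentile 75.6), near the all-gene median of 0.26 there. With the GC trend taken out that value was 0.01 (percentile 97.7). MKI67, a proliferation marker, had 38.2 FPKM against 20.8 FPKM, CENPF, a kinetochore protein, 28.8 FPKM against 18.4 FPKM and CENPE, a kinetochore motor, 5.69 FPKM against 3.40 FPKM. ATF4 genes had a median of 0.48 (percentile 100; 0.19 with the GC trend taken out), with CHAC1 at 4.97 FPKM against 2.56 FPKM and ATF5 at 22.7 FPKM against 14.1 FPKM. The sterol list had a median of 0.38 (0.04 with the GC trend taken out) and histone genes 0.31 (-0.11 with the GC trend taken out). Differences here ran with GC content (Spearman rho across genes 0.62). VHL mRNA itself was at 13.9 FPKM with dTRIM24, 9.04 FPKM with IACS-9571 and 6.94 FPKM with DMSO. CD38, a retinoic acid target, was at 3.92 FPKM with dTRIM24 against 6.96 FPKM with IACS-9571, a difference of -0.70.

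Genes past 2-fold with dTRIM24 against both DMSO and IACS-9571 at 4 h numbered 59 higher and 2 lower, and 58 of the higher ones are histone genes, RMRP, RPPH1 or SNAR genes. The other is MALAT1, which lacks a poly(A) tail too, at 3.58 FPKM against 0.911 FPKM in DMSO and 1.05 FPKM in IACS-9571. The lower genes are SRGAP2B and RNF5. At 24 h 5 genes were higher: PCNA-AS1 (2.25, the smaller of the differences), HYPK (1.98), EIF3CL (1.34), LOC728875 (1.32) and INO80B-WBP1 (1.12). The differences from IACS-9571 carry the all-gene shift of 0.28. With that shift taken off, INO80B-WBP1 falls below the 2-fold bound. EEF1E1-MUTED was lower (-1.60). PCNA-AS1 lies antisense to PCNA, EIF3CL is a copy of EIF3C, and HYPK, INO80B-WBP1 and EEF1E1-MUTED overlap other genes, so these values are uncertain. LOC728875 and INO80B-WBP1 were also past 2-fold lower with IACS-9571 than with DMSO at 4 h, and EIF3CL past 2-fold higher. EIF3C itself was at 260 FPKM with dTRIM24 and 201 FPKM with DMSO at 24 h.

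From 4 h to 24 h in DMSO, 18 genes were higher and 6 lower, with a median of -0.22 over all genes. The counts were 37 and 3 with median centring and 29 and 2 with the GC trend taken out. Sterol genes had a median of -0.32 (percentile 4.69) and differentiation genes -0.45 (percentile 0). Differences here ran with GC content (Spearman rho across genes -0.72), with a median of -0.44 in the genes above 56.6% GC, and the differentiation list has a median GC content of 57.2%. Histone genes had a median of 0.18 in DMSO (percentile 100) and -0.30 in IACS-9571 (percentile 1.05). In IACS-9571 the sterol list had a median of -1.42 with 20 of 23 kept members past 2-fold lower, and 1 gene was higher and 48 lower in all (4 and 21 with the GC trend taken out), with a median of -0.26 over all genes. In dTRIM24 the sterol list had a median of -0.72 with 8 members past 2-fold lower and histone genes -2.63 with 13 of 18. In all 5 genes were higher and 69 lower in dTRIM24, with a median of 0.05 over all genes.

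The effect of each compound relative to DMSO thus differed between times, described here without a test. For IACS-9571 the effect was past 2-fold lower at 24 h than at 4 h in 50 genes, of which 12 are sterol genes and 24 lack a tail, and higher in 6. For dTRIM24 it was lower in 69 genes, of which 59 lack a tail and 6 are sterol genes, and higher in 74. The dTRIM24 counts were 10 higher and 88 lower with median centring, and 14 and 82 with quantile normalization.

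In the other fixed lists HIST2H2BE, of the BET bromodomain list, was the 1 member past 2-fold with dTRIM24 at 4 h. It is also among the 50 histone genes counted above as lacking a poly(A) tail, so it is no separate sign of a BET response. Ribosomal protein genes had a median of -0.16 (percentile 1.15; -0.12 with the GC trend taken out) and proteasome subunits -0.07 (-0.09 with the GC trend taken out). Oxidative phosphorylation subunits had -0.09 (-0.11 with the GC trend taken out) and housekeeping genes -0.12 (-0.09 with the GC trend taken out). The medians of several lists were nearer to 0 with the GC trend taken out: immediate early genes had -0.15 before and -0.01 after, BCL2-family apoptosis genes -0.15 and -0.03, LXR targets -0.21 and -0.04, retinoic acid genes -0.13 and -0.07, metallothioneins -0.14 and -0.08, and MHC class II genes -0.09 and -0.01. The median of p53 targets was -0.07 before and 0.01 after, and that of interferon-stimulated genes -0.02 before and 0.00 after. Heat shock genes had a median of 0.06 (percentile 99.8; 0.04 with the GC trend taken out), BET bromodomain markers 0.09 (0.06 with the GC trend taken out), VHL complex genes -0.05 and HIF targets 0.01. HIST2H2BE in that list had 3.21 FPKM against 0.182 FPKM.

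Markers of other cell types were near the floor of the table. Of T and NK cell markers 1 of 10 was kept (NKG7, at most 32.0 FPKM), and of B cell markers 1 of 8 (PAX5, at most 5.79 FPKM). Erythroid and megakaryocyte markers had 0 of 12 kept, and epithelial and stromal markers 2 of 10 (KRT8, at most 2.46 FPKM, and KRT18, at most 29.7 FPKM). The mitochondrial list had MTRNR2L2 and MTRNR2L8 kept, nuclear relatives of a mitochondrial RNA, with at most 2.37 FPKM and 93.7 FPKM.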

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

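The tests of this part were chosen after the result was seen. A few RNAs lacking a poly(A) tail, 4 with dTRIM24 and 6 with IACS-9571, were past 2-fold higher than DMSO at 4 h and past 2-fold lower at 24 h, and this difference was not tested. DMSO itself differed between the times, with RPPH1 at 2.01 FPKM and 23.5 FPKM and a median over 53 histone genes of 0.382 FPKM and 1.27 FPKM, which enters each value here. The effect of dTRIM24 at 24 h minus that at 4 h was -8.71 for RPPH1, -8.14 for RMRP, -5.58 for HIST1H3B and -4.52 for HIST1H2BG. For IACS-9571 it was -5.02 for RPPH1, -6.36 for SNAR-A6, and -6.24 for SNAR-A1, SNAR-A2, SNAR-A12 and SNAR-A13, which share 1 value. Of the small RNAs left out of the comparisons, 232 reached 1 FPKM in a group. These 232 had a median difference of 0.68 for dTRIM24 at 4 h, with 109 past 2-fold higher and 34 lower. They showed no reversal at 24 h (70 higher and 47 lower).

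For the histone, RNase P and RNase MRP RNAs higher with dTRIM24 at 4 h, a greater share of cells in S phase is the explanation the tables argue against: 13 S-phase genes had a median difference of -0.023 and none was above 0.22, while 53 histone genes had a median of 3.11. Carry-over of RNA without a tail in these libraries may account for the pattern. It predicts that other RNAs without a tail move too, and the small RNAs had a median difference of 0.68 against at most 0.01 in the other comparisons with DMSO. Their median level moved in other groups as well. At 4 h it was 0.861 FPKM in DMSO, 3.82 FPKM in IACS-9571 and 14.2 FPKM in dTRIM24. At 24 h it was 6.46, 1.14 and 6.18 FPKM in the same order. How the libraries were prepared is not given in the sources used here, and an effect of dTRIM24 on these RNAs was not tested and stays open.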

How the results depend on the processing

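No paired analysis was possible because the table holds 1 mean per group; the replicate block and the leave-one-out alternatives were not run, and nothing can be said of the spread between libraries. Of 104 counts under other settings 74 were within 1.5 times of the count reported. All 12 with no filter on low values were among these, nearly by construction. A gene below 1 FPKM in all groups cannot pass 2-fold in a comparison of 2 groups. It can in a change of effect between times, where that of IACS-9571 had 51 lower genes without the filter against 50 with it. So were all 9 with rescaling to the spike-ins, on which the columns already nearly matched. Like counts can also hold different genes. For dTRIM24 against DMSO at 24 h, 12 of 22 calls stayed with median centring, 12 with quantile normalization and 7 without the GC trend. Leaving out RNAs lacking a tail and taking out the GC trend were chosen after seeing the data. Depth is unknown.

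With a pseudocount of 0.1 the genes past 2-fold numbered 67 for IACS-9571 and DMSO at 4 h, 60 for them at 24 h, 116 for dTRIM24 and DMSO at 24 h, 66 for dTRIM24 and IACS-9571 at 24 h, 68 for time in DMSO, 102 for time in IACS-9571, 384 for the change of the dTRIM24 effect and 104 for that of IACS-9571. With 0.5 they were 33 for IACS-9571 and 41 for dTRIM24 against DMSO at 24 h, and 45 for time in DMSO. A smaller pseudocount widens the differences of low genes by construction.

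A 1.5-fold threshold gave 73 and 50 for IACS-9571 against DMSO at 4 h and 24 h, 550 for dTRIM24 against DMSO and 355 against IACS-9571 at 24 h, and 443, 276 and 130 for time in DMSO, IACS-9571 and dTRIM24. For dTRIM24 against IACS-9571 at 24 h a floor of 5 FPKM gave 12, median centring 14, quantile normalization 15 and the GC trend taken out 7. For time, median centring gave 40 in DMSO and 31 in IACS-9571, where quantile normalization gave 32 and the GC trend taken out 25. Without RNAs lacking a tail there were 18 for dTRIM24 and DMSO at 4 h, 7 for dTRIM24 and IACS-9571 at 4 h, 4 for IACS-9571 and DMSO at 24 h, and 9 past 2-fold against both references. By construction a 1.5-fold threshold can only add genes and a floor of 5 FPKM can only remove them. The cause was not tested for the centring, quantile and GC alternatives.

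The histone median at 4 h was 3.32 with a pseudocount of 0.1 and 2.90 with a floor of 5 FPKM against DMSO, and 2.98 and 2.82 against IACS-9571. With the GC trend taken out the sterol medians at 4 h were 1.28 with IACS-9571 and 1.02 with dTRIM24. Among list medians in the outer 5% of random lists, both ends together, those that changed sign for dTRIM24 against IACS-9571 at 24 h were of interferon genes (-0.12 with median centring, -0.068 with the GC trend taken out), metallothioneins (-0.14 and -0.18) and BET markers (-0.16 and -0.11); that of NF-kB genes for dTRIM24 against DMSO at 4 h was 0.018 with the GC trend taken out. Medians of lists nearer the middle changed sign as well with the GC trend taken out, among them histone genes (-0.11) and NF-kB genes (-0.12) for dTRIM24 against IACS-9571 at 24 h. Median centring takes from each group its median log2 value (3.74 for dTRIM24 and 3.44 for IACS-9571 at 24 h), so a positive list median below the difference of these changes sign by construction. Taking out the GC trend takes out the shift of all genes as well. The NF-kB genes have a median GC content of 55.6%. For dTRIM24 against DMSO at 4 h the GC bin with a median of 56.6% had a median difference of -0.14. The median of the NF-kB list was -0.14 too, so taking out the trend brings it near 0 by construction.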

Other observations

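The tests of the uniform shift, of a uniform difference as the whole cause and of transcript length as the whole cause were chosen after the result was seen. Several genes outside the fixed lists were past 2-fold higher with IACS-9571 at 4 h, picked after their values were seen. HSD17B7, a sterol synthesis enzyme outside the list, had 13.6 FPKM in DMSO, 29.5 FPKM in IACS-9571 and 24.7 FPKM in dTRIM24, the last a difference of 0.81. C6orf223 had 2.63, 10.0 and 6.55 FPKM, and SLCO4C1, an organic anion transporter, 1.13, 3.81 and 3.26 FPKM. SREBF1, a regulator of lipid synthesis, was not past 2-fold and had 28.4, 25.9 and 23.6 FPKM at 4 h and 18.3, 19.2 and 33.5 FPKM at 24 h in the same order.

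Some genes with copies or overlapping genes differed between the times in DMSO. H3F3A had 27.2 FPKM in DMSO at 4 h and 115 FPKM in DMSO at 24 h, while H3F3B had 203 FPKM and 166 FPKM. HYPK had 38.3 FPKM in DMSO at 4 h and 4.49 FPKM at 24 h. Among the interferon genes CXCL10, an interferon-induced chemokine, had 2.16 FPKM in DMSO, 4.80 FPKM in IACS-9571 and 3.34 FPKM in dTRIM24 at 24 h.

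The values of most genes were higher with dTRIM24 than with DMSO at 24 h, at a median near that of the 4 h groups. A uniform difference as the whole cause is argued against, since the medians of the highest and lowest of 10 GC bins differed by 0.35 (SD 0.00596 over 1000 resamplings of the genes; the upper bound from shuffled genes was 0.0217). The part of the median shift of 0.26 that does not run with GC content may come from spike-in amount, cell count or RNA per cell, which cannot be told apart, since each gives the same values in 1 mean per group. An error of the spike-in scaling that depends on expression level stays open too. Low, middle and high genes had median shifts of 0.28, 0.27 and 0.22, a difference of 0.052, and the bound set beforehand, from the SD of single spike-ins (0.17), is too wide for a difference of medians (SD 0.0057 over resampled genes).

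Gene-to-gene differences were shared by comparisons without a common group: dTRIM24 minus IACS-9571 at 4 h and DMSO at 24 h minus 4 h had a Spearman rho of 0.54 across 11051 genes, which are not independent replicates. Transcript length as the whole cause is argued against, since the correlation was 0.55 before and 0.54 after taking length out; the test of length set beforehand was undecided, with a smaller rho of 0.14. GC content may account for much of it: the smaller rho was -0.62, and taking GC out lowered the correlation to 0.20. A step of the assay that also moves the spike-ins is in line with their Pearson r of 0.71 over 25 spike-ins (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give; Spearman rho 0.78, two-sided permutation p = 2e-05; both adjusted p = 2e-05 over the 2 correlations; r = 0.79 without the 2 farthest). The spike-ins share the same group means, so these p-values treat single RNAs as units and say nothing of the spread between libraries. An effect of compound or culture time on the genes was not tested and stays open.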
